A study of Mus musculus with 3 samples.

How the data were processed

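Total RNA from splenic tumours of 3 mice was labelled with Cy3 and hybridised to 1 Agilent mouse expression array per tumour, per the labels' protocols. The labels give 1 tumour of p53+/− genotype and 2 tumours of the LSD1 × p53+/− genotype, numbered 2 and 3, here called the p53 tumour, LSD1 tumour 2 and LSD1 tumour 3. The growth protocol speaks of isolated splenic cells of mice aged 10 weeks, while the tissue label reads splenic tumour, and all 3 animals are labelled male. The labels do not say what the LSD1 element of the genotype is, so it is read here only as the group's name. No pooling of animals is stated. The number after the genotype names a mouse or a line, which the labels do not settle. The p-values of single genes measure only the spread between these samples. Those of the main test of gene lists rest on the spread across genes, as given below.

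Each scan was deposited as the output of Agilent Feature Extraction 11.5.1.1, per the file headers and the submitters' processing notes. The value used was the processed signal, a linear intensity that the software had background-subtracted and detrended within the array, per the file headers, without scaling between arrays. The median pixel intensity of each spot and of its local background, and the per-spot flags for signal well above background, saturation and outliers, were also deposited and used. Each array held 62976 spots, 59305 of them not controls. The share of these well above background was 55.6% for the p53 tumour, 52.8% for LSD1 tumour 2 and 51.5% for LSD1 tumour 3. No spot was saturated, between 113 and 128 spots per array carried an outlier flag, and 10 of 10 of the software's quality metrics were in range on every array. The p53 tumour and LSD1 tumour 3 shared slide 1 and scan 1, and LSD1 tumour 2 was on slide 2 and scan 2. A second deposited table held the same intensities multiplied by 1 factor per array (1.06, 0.779 and 0.902 in the order above), as found by setting it against the processed signals. What the authors set those factors on is not stated. The medians of its columns were 64.2, 54.2 and 43.5.

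The processed signal was scaled to the array's 75th percentile (608, 712 and 554 in the same order) and taken as log2. Outlier spots were left out, and spots of 1 probe were averaged (300 probes had 10 spots each). The design had planned on a symbol column of the scanner files, and probes were instead named through their RefSeq accessions in the supplied gene table of assembly GRCm38.p6, which was used for names only. The array's own build is mm9, so no coordinates are given. Of 47837 probe identifiers 25126 matched, which named 32994 of the 56605 non-control probes and left 23611 unnamed. A gene was represented by its probe with the highest mean log2 signal. Genes whose probe was well above background on at least 1 array were tested: 15240 of 22908, of which 12812 were above background on all 3. Where the dimmer side was not well above background, a fold is given as "at least" for this scaling, against the higher of that array's lowest level well above background and the probe's own value.

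The LSD1 × p53+/− genotype was compared with p53+/− with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with Benjamini-Hochberg adjustment, threshold 0.05). With 1 array against 2 the fit has 1 residual degree of freedom and 3.27 in all with the prior, and it assumes that the lone p53 tumour varies like the LSD1 tumours. Genes at least 2-fold from the p53 tumour in the same direction in both LSD1 tumours, and genes at least 2-fold apart between the LSD1 tumours, were counted by size with no test. The brighter side had to be well above background. For a gene higher in both LSD1 tumours that meant both LSD1 arrays, and for a lower gene the p53 array alone. A total of 27 gene lists was tested with camera at a preset correlation of 0.01, adjusted over the lists. At that setting camera takes genes as nearly independent. Its p-values then reflect the spread of differences across genes and do not measure the spread between tumours. Per tumour, each list's median difference from the p53 tumour was set against 10000 random lists of the same size matched on mean expression in 10 bins. List medians are given less the median of all tested genes in that tumour, a choice made after the data were examined. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. That rule took Kdm1a and Trp53, the 10 highest and 10 lowest genes by the smaller of both tumours' differences, up to 4 members per list with the largest mean difference, and the 5 genes highest in each LSD1 tumour over the other. Its ranking includes values at the background level, so no order is stated among genes with a bound. Any other gene named was chosen after its values were seen.

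The steps were tested on simulated data with the spread between the 2 LSD1 tumours. Among 15240 genes, limma called 0 of 50 genes changed by 1, 2, 4 or 6 log2 units. The 2-fold count, here without the condition on background, found 18, 35, 49 and 49 of 50, along with 1983 unchanged genes. With a spread of 0.1 of that between the tumours, limma called 46 of 50 genes changed by 1 log2 unit and 50 of 50 at each larger size. A shift of 1 log2 unit in a 20-gene list was called in 99 of 100 simulations with the preset correlation and in 0 with an estimated one, and 6 of 2600 unshifted lists were called. Noise was drawn independently for each gene, so these rates do not cover lists whose members vary together. The estimated correlation was 0.46 for B cell genes and 0.82 for G2 and mitosis genes. With 1 residual degree of freedom it reflects only how many members were higher in 1 LSD1 tumour than in the other. It is therefore no measure of how far members vary together across tumours.

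Alternatives were normexp background correction with an offset of 50, quantile normalization, the authors' value table, other filters on dim probes, the mean over a gene's probes, eBayes with trend and robust settings, an adjusted p of 0.1, a 3-fold size, camera with an estimated correlation or on ranks, and each LSD1 tumour left out in turn. Normexp had been planned on the mean pixel signal and was run on the median pixel signal in its place. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.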

Results

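Gene expression was measured on 1-colour arrays in tumours that had developed in the spleens of p53-haploinsufficient mice at 10 weeks of age. The p53+/− genotype was represented by 1 tumour and the LSD1 × p53+/− genotype by 2. LSD1 is the histone demethylase encoded by Kdm1a. The design asks how tumours with the LSD1 element differ from the tumour with p53 haploinsufficiency alone. Values are log2 signals relative to each array's 75th percentile, for 15240 genes above background on at least 1 array. The number of arrays limits the precision of every comparison.

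Transcripts of the genes named in the genotypes differed little. Kdm1a was higher than in the p53 tumour by 1.56-fold in LSD1 tumour 2 and by 1.17-fold in LSD1 tumour 3 (limma, adjusted p = 0.972). In LSD1 tumour 3 that direction turned with quantile normalization (-0.04 log2) and in the authors' value table (-0.14 log2). Trp53, which encodes p53, was 1.51-fold and 1.23-fold lower in LSD1 tumours 2 and 3 (adjusted p = 0.969). Each gene has 1 probe among those named, and a transgene lacking the probe's target would go unseen, so these levels check the labels only in part.

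The largest measured difference shared by both LSD1 tumours was in Cdkn2a, which encodes the cell cycle inhibitor p16INK4a and the p53 activator p19ARF. Its signal was 204-fold higher in LSD1 tumour 2 and 191-fold higher in LSD1 tumour 3 than in the p53 tumour. The second Cdkn2a probe, not above background in the p53 tumour, was higher by at least 4.19 and 4.16 log2 units. Ccl8, a chemokine for monocytes, was 33.7-fold and 121-fold higher. With normexp these sizes fell, to 6.79 and 6.61 log2 units for Cdkn2a and to 3.68 and 5.39 for Ccl8. The normexp offset of 50 shrinks differences of dim probes, and 64 of the 69 bounds that named genes had against the p53 tumour were not reached. Each fold given as "at least" therefore holds for the scaling used here. With normexp Ccl12 was higher by 2.79 and 1.95 log2 and Cd209a lower by 3.17 and 3.01, the dimmer side of each not being above background. Bounds only could be given for the other 8 genes taken as highest, which were not above background in the p53 tumour. In LSD1 tumours 2 and 3 these were at least 18.1-fold and 9.02-fold for the chemokine Ccl12, 40.4-fold and 18.7-fold for the peptidylarginine deiminase Padi3, 22.2-fold and 26-fold for the neuropeptide Nts, and 12.1-fold and 6.46-fold for Erfe, the erythroid regulator of hepcidin. Lvrn, Fzd6, Lhfpl3 and Mc3r completed that set. Other probes of Lvrn, Lhfpl3 and Erfe were not above background on any array and give no check. Among the 10 lowest, the complement receptor gene Cr2 was measured on all 3 arrays and was 19.5-fold and 163-fold lower. The dendritic cell lectin Cd209a was at least 17.7-fold and 17.8-fold lower, Crip3 at least 14.2-fold and 14.3-fold lower, and Igfbp5 at least 10.3-fold and 10.4-fold lower. Rapgef4, Mlc1, Kcnj11, Ankrd60, Prkaa2 and Skint1 completed the lowest set, with bounds between 3.34-fold and 5.15-fold. Other probes of Ankrd60, Prkaa2 and Skint1, and 1 of the other Rapgef4 probes, were not above background on any array. No gene passed limma's adjusted threshold, Cdkn2a included (lowest adjusted p = 0.967). Adjusted over the list alone, Cdkn2a passed among 17 tumour suppressor genes (adjusted p = 0.00564) and Cd209a among 14 dendritic cell genes (adjusted p = 0.0197), the 2 such calls in all lists. Cd209a was above background in the p53 tumour alone, so its call rests on background-level values in both LSD1 tumours. Among the other tumour suppressors, Cdkn2b, the neighbouring cyclin-dependent kinase inhibitor, was 1.96-fold and 6.14-fold higher and Ezh2 2.14-fold and 2.79-fold higher (0.56 and 0.61 log2 by the least of its other probes), and the list as a whole missed the camera threshold (adjusted p = 0.123).

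**Figure D1:**
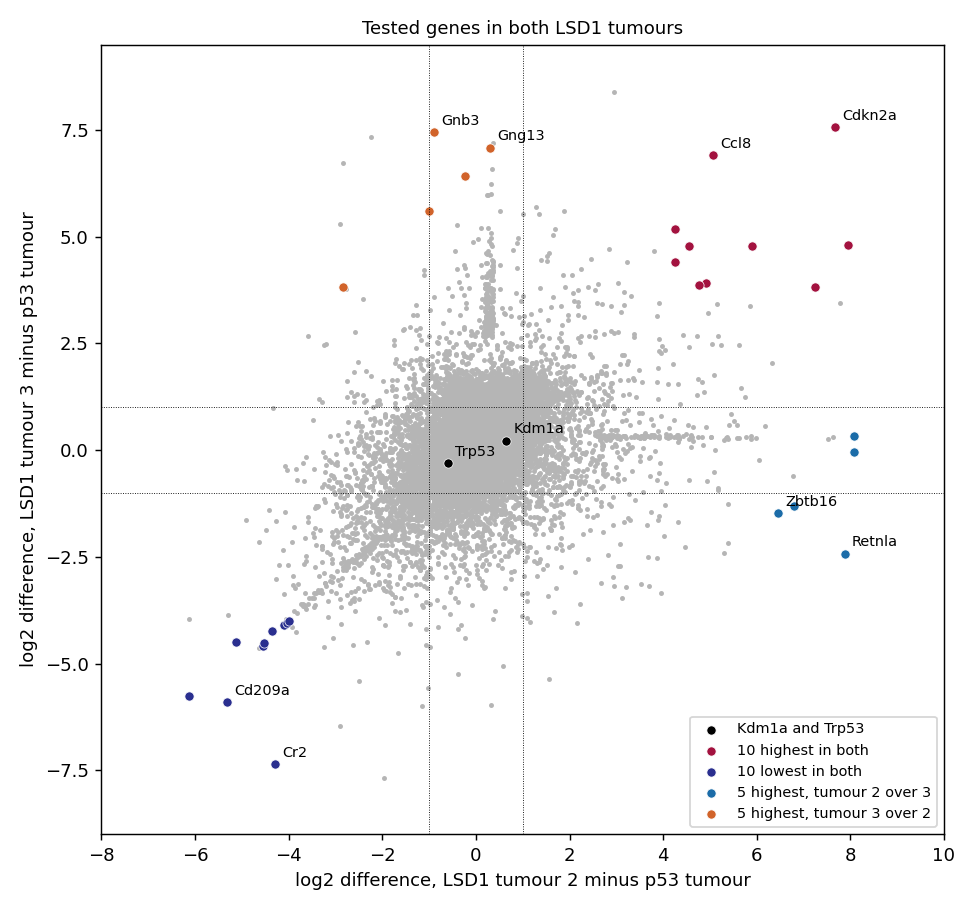
Log2 difference from the p53 tumour of every tested gene in LSD1 tumour 2 (horizontal axis) and LSD1 tumour 3 (vertical axis), with the named genes coloured and dotted lines at a 2-fold difference. Cdkn2a lies at 7.68 and 7.57, Cr2 at -4.29 and -7.35, and the narrow bands parallel to the axes are mostly genes not above background in the p53 tumour and in 1 of the LSD1 tumours.

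Across the transcriptome the LSD1 tumours were not the closest pair. The SD of the log2 difference over genes was 1.22 between the 2 LSD1 tumours, and 1.09 and 1.11 between the p53 tumour and LSD1 tumours 2 and 3. Pearson's r across genes, which are not independent replicates, was 0.911 for the LSD1 pair and 0.924 and 0.927 for the others. The median absolute log2 difference placed the LSD1 pair (0.53) between the p53 tumour's distances from LSD1 tumours 2 and 3 (0.52 and 0.59). limma called 0 of 15240 genes at an adjusted p of 0.05, and 568 had an unadjusted p under 0.05 (175 higher, 393 lower), where chance gives 762. By size, with the brighter side above background, 531 genes were at least 2-fold higher and 820 at least 2-fold lower in both LSD1 tumours, 39.3% of them higher. The condition asks for 2 arrays for a higher gene and 1 for a lower gene, so it adds to the excess of lower genes. Among genes above background on all 3 arrays the order turned, with 447 higher and 416 lower. In the authors' value table, whose scaling moves the median difference of all genes from 0.05 and 0.16 to -0.16 and -0.20 in LSD1 tumours 2 and 3, the split was 219 higher and 1266 lower, 14.7% higher. Both differences share the p53 array. Their correlation across genes was 0.381 and their covariance 0.460. A simulation of 3 unchanged arrays gave 0.50 and 0.752, with every array given the spread of the LSD1 pair, the widest of the 3 pairs by SD. Without the condition on background, 628 genes were 2-fold higher and 820 lower in both, where the simulation gave 976 and 979 and independent lists would share 284 and 212. The wide simulated spread raises the simulated covariance and counts, so lower observed values do not show less overlap than chance gives. The simulated correlation of 0.50 comes from giving every array the same spread, whatever its width. The observed correlation and covariance follow from the 3 SDs between arrays given above, so they add nothing to those. The lone p53 array cannot be split, so part or all of any overlap may come from it. Slide 1 held both genotypes, and with slide as a block the genotype difference equals that of LSD1 tumour 3 from the p53 tumour, which on its own left 2321 genes at least 2-fold higher and 1749 lower. LSD1 tumour 2 alone gave 1777 and 1750.

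Genes of B cells, plasma cells, dendritic cells and NK cells were lower in both LSD1 tumours. Of 20 B cell genes, 19 were lower in both, with medians relative to all genes of -2.55 in LSD1 tumour 2 and -1.22 in LSD1 tumour 3 (camera adjusted p = 3.01e-10). Fcmr, the receptor for IgM, was 12.0-fold and 2.98-fold lower. Fcer2a, encoding CD23 of follicular B cells, was 3.90-fold lower in LSD1 tumour 2 and at least 111-fold lower in LSD1 tumour 3. Of 10 plasma cell genes 8 were lower in both (medians -2.16 and -0.62, adjusted p = 0.000139), among them Jchain, the joining chain of secreted antibodies, by 4.87-fold and 9.55-fold. Of 14 dendritic cell genes 11 were lower in both (medians -1.19 and -0.88, adjusted p = 8.10e-06), including Clec9a, a receptor of cross-presenting dendritic cells, by 10.8-fold and 3.52-fold and the growth factor receptor Flt3 by 6.39-fold and 4.52-fold. Of 15 NK and cytotoxic cell genes 9 were lower in both and 1 higher (medians -1.72 and -1.52, adjusted p = 8.46e-06). The NK receptor gene Klrd1 was 7.5-fold and 4.86-fold lower and Ncr1 at least 4.50-fold and 4.54-fold lower. The stromal list was also lower by test (adjusted p = 0.0411), with 9 of 21 members lower in both and medians of -0.07 and -0.83, but missed the threshold with camera on ranks (adjusted p = 0.0596) and in the authors' value table (adjusted p = 0.0582). Its largest differences were in Cxcl13 (14.3-fold and 19.2-fold lower), the chemokine of B cell follicles, in Ccl19 (4.60-fold and 1.90-fold lower), the chemokine of T cell zones, and in the matrix gene Dcn (3.82-fold and 3.73-fold lower). Notch targets were lower (9 of 11 in both, medians -1.32 and -0.96, adjusted p = 0.000369), with Dtx1 12.5-fold and 4.17-fold and Hes1 3.45-fold and 3.46-fold lower, while Myc, which many other signals control, was 4.10-fold and 2.16-fold higher. None of the 10 lists called held with an estimated correlation (adjusted p = 0.648 with an estimated correlation for each of the 10). That setting also called a list truly shifted by 1 log2 unit in 0 of 100 simulations. With 1 residual degree of freedom it could hardly call any list, so these lost calls do not decide whether the lists differ.

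**Figure D2:**
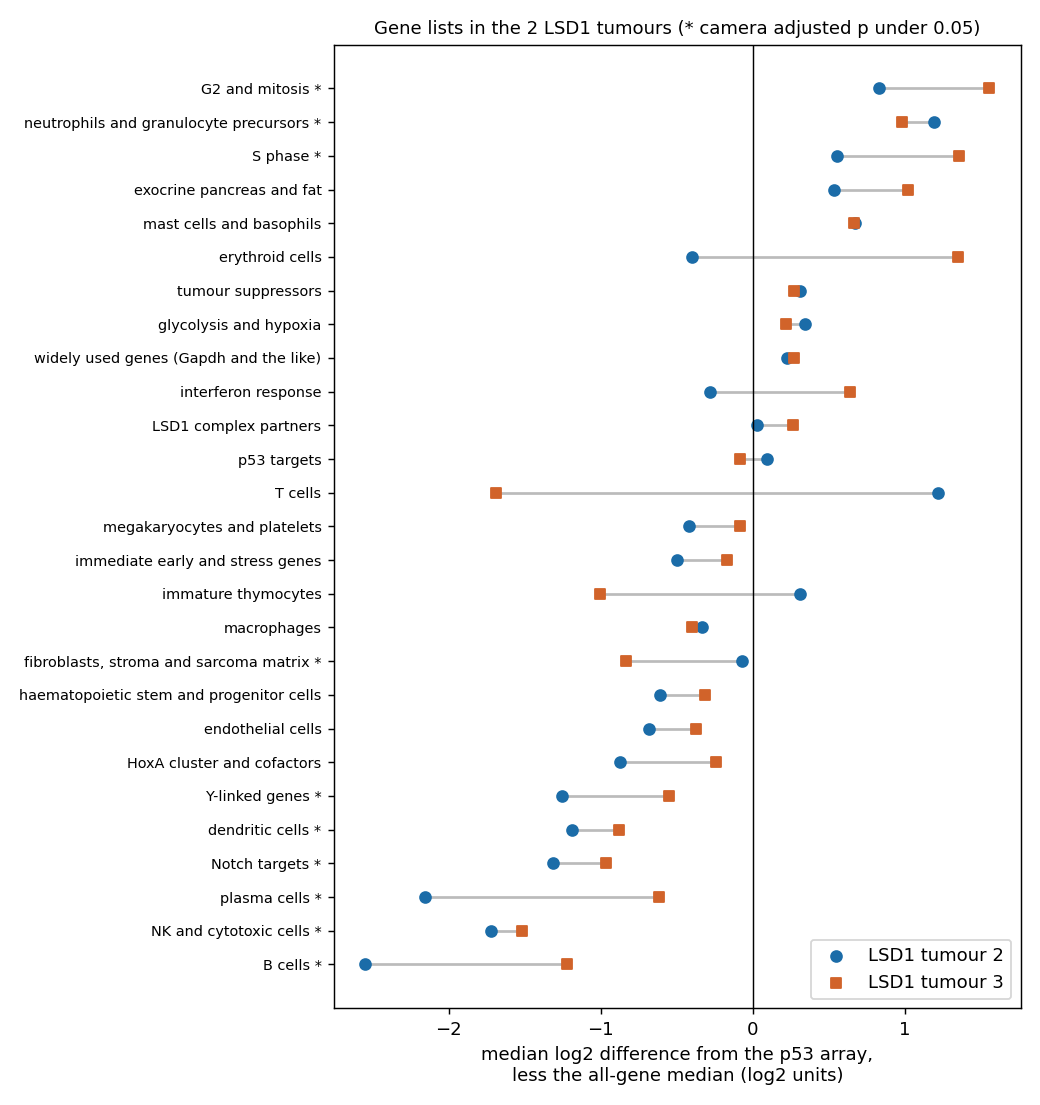
Median log2 difference from the p53 tumour, less that of all tested genes, for each of the 27 gene lists in LSD1 tumour 2 (circles) and LSD1 tumour 3 (squares), with a line joining the 2 tumours. B cell genes lie at -2.55 and -1.22 (the lowest in LSD1 tumour 2), G2 and mitosis genes at 0.83 and 1.55 (the highest in LSD1 tumour 3), and T cell genes at 1.22 and -1.69 (the highest in LSD1 tumour 2 and the lowest in LSD1 tumour 3).

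Cell cycle genes and genes of neutrophils and their precursors were higher in both LSD1 tumours. All 22 genes of G2 and mitosis were higher in both, with relative medians of 0.83 and 1.55 (adjusted p = 1.12e-09), although 1 of them turned in LSD1 tumour 2 with quantile normalization, where 21 were higher in both. The spindle checkpoint kinase gene Ttk was 3.77-fold and 4.81-fold higher (0.48 and 1.77 log2 by the least of its other probes), the mitotic kinase gene Cdk1 2.64-fold and 4.25-fold, and the mitotic transcription factor gene Foxm1 3.11-fold and 2.97-fold. Of 20 S phase genes 17 were higher in both and none lower in both (medians 0.55 and 1.36, adjusted p = 7.99e-07). The replication helicase genes Cdc45 and Mcm2 were 2.80-fold and 4.76-fold, and 2.83-fold and 2.60-fold, higher. Of 17 neutrophil genes 14 were higher in both and 2 lower in both (medians 1.19 and 0.98, adjusted p = 1.99e-05). The granule protease genes Ctsg and Prtn3 were 3.74-fold and 5.30-fold, and 2.65-fold and 3.92-fold, higher. The chemokine receptor gene Cxcr2, active in mature neutrophils, was 2.28-fold and 5.94-fold lower, and Mmp9 and Retnlg, chosen after their values were seen, differed by -0.04 and 0.01 log2 in LSD1 tumour 2 and by -0.99 and -0.89 in LSD1 tumour 3. These 3 lists too lost their call with an estimated correlation (adjusted p = 0.648 with an estimated correlation), a setting that could hardly call any list here.

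Among the lists, the medians of the 2 LSD1 tumours lay furthest apart for T cell and erythroid genes. Of 24 T cell genes, 19 were higher than in the p53 tumour in LSD1 tumour 2 and none in LSD1 tumour 3, with relative medians of 1.22 and -1.69, above and below all 10000 random lists (1 gene was higher in LSD1 tumour 3 with normexp and with quantile normalization). The costimulatory receptor gene Cd28 was higher by 3.17 log2 units in LSD1 tumour 2 and lower in LSD1 tumour 3 (-1.68), the T cell transcription factor gene Gata3 stood at 3.67 and -2.51, and Cd3d, of the T cell receptor complex, at 2.36 and -1.54. Cd8a and Cd8b1, which encode the coreceptor of cytotoxic T cells, were lower in both tumours, by 11.1-fold and 3.83-fold and by 14.8-fold and 3.50-fold, as was Ccr7, the homing receptor for lymphoid tissue (3.74-fold and 6.06-fold). The other Cd8a probe, above background on all 3 arrays, gave smaller differences of -1.14 and -1.75 log2 units. The mean over both tumours was -0.42, opposite in sign to the median of LSD1 tumour 2, and camera gave an adjusted p of 0.0937. Immature thymocyte genes had medians of 0.31 and -1.0 (adjusted p = 0.229), with Dntt, the template-independent polymerase of antigen receptor joining, 7.15-fold and 4.0-fold lower, and Tox 5.62-fold higher in LSD1 tumour 2 and 1.83-fold lower in LSD1 tumour 3. Erythroid genes went the other way: all 24 were higher in LSD1 tumour 3 and 4 in LSD1 tumour 2 (medians 1.34 and -0.40, adjusted p = 0.0937), although 23 and 22 were higher in LSD1 tumour 3 with quantile normalization and in the authors' value table. The erythroid transcription factor gene Klf1 was 4.09-fold higher in LSD1 tumour 3 and 1.12-fold lower in LSD1 tumour 2. Interferon response genes had medians of -0.28 in LSD1 tumour 2 and 0.64 in LSD1 tumour 3 (adjusted p = 0.304), with Oasl2 1.21-fold and 4.35-fold higher. The macrophage list as a whole was close to the threshold (medians -0.34 and -0.40, adjusted p = 0.0787), with 7 of 19 members higher in each LSD1 tumour. In LSD1 tumour 3 the phosphatidylserine receptor gene Timd4 was 15.4-fold lower, the marginal zone receptor gene Marco 7.43-fold lower and Siglec1, a gene of marginal metallophilic macrophages, at least 8.96-fold lower. In LSD1 tumour 2 these 3 differed from the p53 tumour by 1.1, 0.03 and 0.58 log2 units, Marco with the opposite sign after quantile normalization (-0.22) and in the authors' value table (-0.19).

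**Figure D3:**
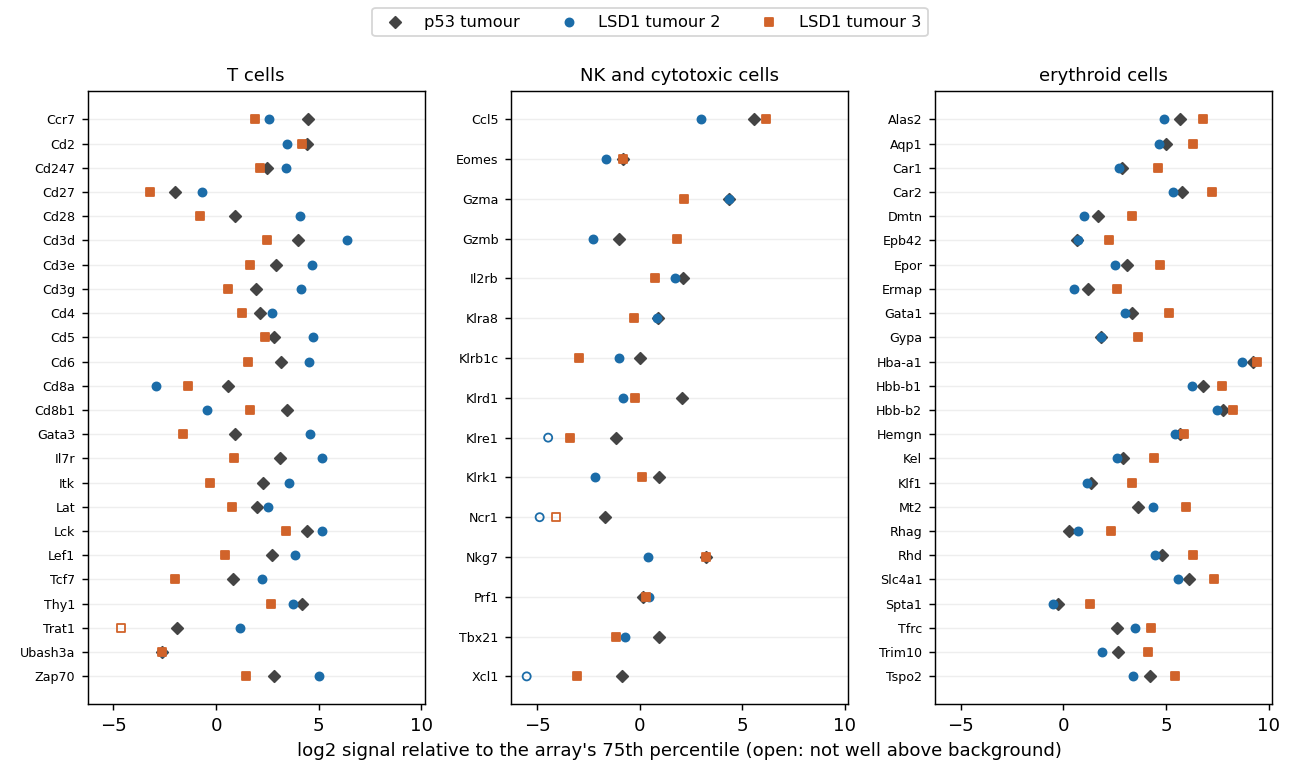
Log2 signal relative to the array's 75th percentile of each measured T cell, NK and cytotoxic cell, and erythroid gene in the p53 tumour (diamonds), LSD1 tumour 2 (circles) and LSD1 tumour 3 (squares), with open symbols where a signal was not well above background. Cd3d stands at 4.0, 6.37 and 2.46, and Klrd1 at 2.07, -0.83 and -0.21.

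In single genes, LSD1 tumour 2 exceeded LSD1 tumour 3 by at least 2-fold in 1692 genes and was exceeded in 2140 (2054 and 1788 in the authors' value table, where the order turned). The total of 3832 genes lies between the 3527 and 4070 that were 2-fold apart between the p53 tumour and LSD1 tumours 2 and 3. Taken as highest in LSD1 tumour 2 over LSD1 tumour 3, by a ranking that includes values at background, were Retnla, a product of macrophages exposed to type 2 cytokines (at least 317-fold), Zbtb16, the transcription factor of innate-like T cells (at least 242-fold), the glutamate transporter gene Slc1a6 (at least 66.7-fold), Gpnmb (at least 65.8-fold) and Myh3 (at least 54.7-fold), whose other probe was not above background on any array. In the other direction, Gnb3 and Gng13, subunits of G proteins in sensory cells, were at least 140-fold and 23.3-fold higher in LSD1 tumour 3, the actin regulator gene Avil at least 45.7-fold, the acute phase gene Saa3 at least 24.3-fold and Nxpe5 at least 24.1-fold.

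The lists tied to the genotypes themselves did not pass the test. Of 22 p53 targets, 11 were higher and 4 lower in both LSD1 tumours (4 and 11 in the authors' value table), with medians of 0.09 and -0.08, a mean of -0.02 and a camera statistic in the upward direction (adjusted p = 0.923). Gtse1 was 3.67-fold and 3.34-fold higher and the p53-inducible Rrm2b 2.46-fold and 2.64-fold lower. Partners of LSD1 in chromatin complexes had medians of 0.03 and 0.26 (adjusted p = 0.519), with the repressor gene Gfi1 4.11-fold and 2.70-fold higher and Phf21a 3.07-fold and 2.52-fold lower. The HoxA cluster and its cofactors had medians of -0.87 and -0.24 (adjusted p = 0.0787), with Hoxa7 2.70-fold and 3.00-fold and the cofactor gene Meis1 1.77-fold and 2.41-fold lower.

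Lists for other cells and states completed the comparison, and of these the Y-linked list alone passed, while endothelial genes, which missed the threshold, were called lower under 7 of 8 alternatives. The 4 measured Y-linked genes were lower in both tumours (medians -1.26 and -0.55, camera adjusted p = 0.0386), Kdm5d by 3.33-fold and 1.70-fold. With an estimated correlation, which could hardly call any list here, camera's adjusted p was 0.648. The call at the preset correlation was lost with quantile normalization (adjusted p = 0.0645) and without a filter on dim probes (adjusted p = 0.115). Genes of exocrine pancreas and fat had medians of 0.53 and 1.02 (adjusted p = 0.174). The pancreatic enzyme genes Amy2a5 and Cela2a were at least 88.8-fold and 35.4-fold higher in LSD1 tumour 3 than in the p53 tumour, and Adipoq, a fat cell hormone gene chosen after its values were seen, was above background in LSD1 tumour 2 alone. Cfd, another fat cell gene of that list, was above background in the p53 tumour alone on both of its probes. Mast cell and basophil genes had medians of 0.67 and 0.67 (adjusted p = 0.0576), with the mast cell protease gene Cpa3 at least 7.29-fold and 3.35-fold higher. Of its 11 members 7 were higher in both tumours and 2, Kit and Cma1, lower in both. Cma1 was not above background in LSD1 tumour 3. Medians were -0.68 and -0.37 for endothelial genes (adjusted p = 0.0633), -0.61 and -0.32 for stem and progenitor cell genes (adjusted p = 0.0633), and -0.42 and -0.09 for megakaryocyte genes (adjusted p = 0.341). They were -0.50 and -0.17 for immediate early genes (adjusted p = 0.0963), with Fos 5.34-fold and 1.78-fold lower, and 0.35 and 0.21 for glycolysis and hypoxia genes (adjusted p = 0.201), with the hypoxia-responsive Adm 20.1-fold higher in LSD1 tumour 3 and 1.08-fold higher in LSD1 tumour 2, where it was lower in the authors' value table (-0.11 log2). Widely used control genes had medians of 0.22 and 0.27 (adjusted p = 0.0633), and Gapdh was 2.91-fold and 2.45-fold higher.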

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

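The tests of single probes, of the slide, of p53 activity and of dilution were chosen after the results were seen. The predictions for the groupings of the 2-fold genes and of the gene lists were also written then. Probes left without a gene name entered none of the comparisons above, and 403 of them were at least 2-fold higher than the p53 array on both LSD1 arrays, beside 1267 at least 2-fold lower, out of 11079 above background on at least 1 array.

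With 3 arrays there are 3 ways to set 1 against 2, so no share under 0.05 can be reached. The real grouping gave 0 limma calls, as did both others, and all 3 groupings gave a count as large. It gave 1351 genes at least 2-fold from the lone array in both others, and the highest other grouping gave 1823, so 3 of 3 groupings gave as many. It called 10 gene lists, the highest other also called 10, and 2 of 3 groupings called as many.

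Cdkn2a was far brighter on both LSD1 arrays than on the p53 array. A single faulty probe is argued against by the second Cdkn2a probe, whose smaller difference was at least 4.16 log2 units. LSD1 tumour 3, which shared the p53 tumour's slide, differed by 7.57, so a difference between slides cannot account for that value. Cdkn2a was picked for being far higher in both tumours, so this outcome was fixed beforehand and is no separate test of the slide. A lower p53 activity in the LSD1 tumours, which would leave Cdkn2a less restrained, stays open: the median of the p53 target list lay at the 73.1st percentile of random lists in LSD1 tumour 2 and the 35.6th in LSD1 tumour 3, and its members went both ways, so it may or may not be at work. A genotype effect also stays open, since 1 p53 tumour cannot show whether a low Cdkn2a level is typical of its genotype.

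The lists of B cells, dendritic cells and NK cells had lower medians in both LSD1 tumours. None kept its camera call with an estimated correlation, a setting that could hardly call any list with these 3 arrays. Of 15 NK and cytotoxic cell genes, 9 were lower in both. If tumour cells had diluted all normal spleen cells equally, the macrophage, megakaryocyte and endothelial lists would have been lowered as much as the B cell list. The middle one of those 3 gaps was 2.13 log2 units in LSD1 tumour 2 and 0.85 in LSD1 tumour 3, and 5 of the 6 gaps exceeded 2 bootstrap standard errors. These errors come from resampling list members on 1 array. The errors do not measure the spread between tumours, and members may vary together, which these arrays cannot measure. By their medians the lists were not lowered equally on these arrays, but whether equal dilution was the whole cause is left undecided. In LSD1 tumour 3, on the p53 tumour's slide, the highest of the 3 lists lay at the 0.04th percentile, so a difference between slides cannot account for the low medians there. The 3 lists were picked for being low in both tumours, so this is no separate test of the slide. A loss of particular lymphoid and dendritic cells in the LSD1 genotype, and an unusual p53 tumour rich in them, may each account for it and cannot be told apart with 1 p53 array.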

How the results depend on the processing

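Quantile normalization, the authors' value table, 2 other filters, probe means, normexp, trend and robust settings and an adjusted p of 0.1 all left 0 limma calls. The scale of the median of tested genes and the inclusion of every probe identifier, both chosen after seeing the data, did too. Each of the 137 values of named genes, taken over both LSD1 tumours or between them, kept its direction under every alternative that measured it with both LSD1 tumours. Most of these genes were picked from these data for large differences, and some alternatives cannot change a value, so kept directions were largely fixed beforehand. With LSD1 tumour 2 left out 3 of 127 values turned (Tox, Itgb3 and Gp6), and with LSD1 tumour 3 left out 7 did (Rcor2, Satb1, Siglec1, Marco, Timd4, Klf1 and Hlf). Across scalings, values in 1 tumour turned for Kdm1a, Marco and Adm, as given above, and for Gng13, Myh3, Cpa1, Tubb1 and Gp6. Genes 2-fold apart in both LSD1 tumours numbered 325 higher and 398 lower with normexp, 219 and 1266 in the authors' value table, 447 and 416 among genes above background on all 3 arrays (fewer genes tested), where the excess of lower genes turned, 106 and 350 at 3-fold, and 921 and 2045 over every identifier. With a single LSD1 tumour they ranged from 1777 to 2321 higher and from 1749 to 1750 lower, since fewer samples had to agree. Between the LSD1 tumours, genes higher in LSD1 tumours 2 and 3 numbered 960 and 1539 with normexp, 951 and 1519 above background on all 3 arrays, and 2054 and 1788 in the authors' value table, where the order turned. At 3-fold 969 were higher in LSD1 tumour 2 and 1074 in LSD1 tumour 3, and over every identifier 3448 and 3281, again turned. Lists called numbered 16 with the filter on all 3 arrays and 16 with probe means, and 0 with an estimated correlation, which could hardly call any list here. Endothelial genes, not called above, were called lower under 7 of 8 alternatives, macrophage genes under 4 and T cell and immediate early genes under 3 each. Stem cell genes were called lower under 2 and HoxA genes under 1. Lists with a mean above that of all genes were called too: mast cell genes under 3, control genes under 2, and erythroid and pancreas and fat genes under 1 each. The mean of the p53 target list turned to 0.00483 with probe means. The causes of these changes were not tested, beyond those given. Dim probes limit the folds to bounds, and 64 of 69 bounds against the p53 tumour and 19 of 22 between the LSD1 tumours were not reached with normexp. No analysis paired by replicate number was possible because the genotypes share none, and slide as a block leaves no residual degree of freedom for a test.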

Other observations

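The genes in this paragraph were chosen after their values were seen. Relative to the p53 tumour, the type 2 cytokine gene Il4 was 45.6-fold higher in LSD1 tumour 2 and 1.62-fold higher in LSD1 tumour 3. Il17rb, a receptor subunit for IL-25, was 51.0-fold and 2.73-fold higher, and Pdcd1, which encodes PD-1, 13.5-fold and 1.67-fold higher. Icos, a costimulatory receptor gene, was 39.6-fold higher in LSD1 tumour 2 and 5.32-fold lower in LSD1 tumour 3. Arg1, an enzyme of macrophages exposed to IL-4, was above background in LSD1 tumour 2 alone and at least 12.2-fold higher there than in the p53 tumour. Foxp3, the transcription factor of regulatory T cells, was 1.44-fold lower in LSD1 tumour 2.

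The marker list in this paragraph was written before its values were examined, and the test of the second Avil probe was chosen after. Gnb3, Gng13 and Avil were bright on the array of LSD1 tumour 3 alone, and all 3 are genes of tuft cells, the chemosensory cells of epithelia. A single faulty probe is argued against by the second Avil probe, which was at least 2.32 log2 units higher there than on both other arrays. Of 17 other tuft cell markers, 15 had a probe, 10 could be tested and 8 of those were also above background in the p53 tumour. The rest of the 15 were not above background on any array, LSD1 tumour 3 included, and leaving them out raises the share given next. Of the 10, 4 (Trpm5, Rgs13, Krt18 and Hepacam2) were at least 2-fold higher in LSD1 tumour 3 than on both others, or 40%, between the limits of 50% and 20% set for and against tuft cells as a candidate source, so the test left it open. Trpm5, the ion channel of these cells, stood at -1.61 in LSD1 tumour 3 and was not above background elsewhere, while Dclk1 was lower there (-2.17) than in the p53 tumour (0.47).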
